A study of Danio rerio with 4 samples.

How the data were processed

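RNA had been extracted from the caudal peduncle of 4 adult zebrafish of the AB strain, 7 days after cryoinjury. The pieces included a margin of 1 to 2 mm around the wound, and skin and bones were removed, per the labels' protocols. Stranded libraries were made from polyadenylated RNA, per the labels' protocols. The fish were kept at 28 °C with 14 h of light and 10 h of dark, per the labels.

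The values are RSEM expected counts per gene, as the authors deposited them in 1 table of the series. The submitters' processing notes name fastp 0.23.4, STAR 2.7.11a and RSEM 1.3.3. The genome build and the gene annotation are not given in the sources used here. The table held 32520 gene IDs and 4 columns for the samples of the series. Another 4 columns in the table carry names of samples outside the series and were not used in any step, so injured muscle was not compared with uninjured muscle. Between 4.96% and 6.38% of the values above 0 per library were not whole numbers exactly as deposited. RSEM divides reads that match several genes, and closely related copies may share reads. Counts were rounded to whole numbers.

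The deposited totals were 8608404, 9223182, 13151341 and 8035167 estimated counts. A count of 0 allows up to 3 counts, or 0.348, 0.325, 0.228 and 0.373 CPM in fish 1 to 4. Shares of counts in 1 library have exact 95% Clopper-Pearson intervals. Intervals and floors cover counting error only. The series describes the 4 samples as biological replicates, and the p-values for single genes and for ratios measure the spread between these 4 samples. The p-values of gene lists are ranks among random gene lists, in which genes are the units, and they describe these libraries. No 2 libraries agreed within sampling noise (chi-square per gene between 23.2 and 70.1), and Spearman correlations across all genes lay between 0.935 and 0.953. Genes are not independent replicates in such a correlation.

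Symbols came from a table that pairs gene IDs with names and covers 29201 of the 32520 IDs. It gives many zebrafish genes a symbol in human style without the letter that marks a duplicate. The 28 gene lists held 529 names. Of these, 372 matched by name, 124 matched a symbol once the letter was dropped (all IDs with that symbol then entered the list) and 33 matched none. This matching rule was set after the names, but not the values, had been seen. The lists held 534 IDs, and no ID was in more than 1 list. The lists, tests, pairs and the rule for named genes were fixed before the data were examined. Named genes were the 20 genes with the highest mean CPM, the 3 most abundant members of each list together with any list member called variable, the 20 called genes with the largest dispersion ratio, both genes of each pair, and pax7a, pax7b, myf5, myod1, myog, myf6, mymk and mymx. Genes without a symbol were not named under this rule. Not every gene under the rule is given in the text. The further list members il1b, IL10, mki67, hsp90aa1.1, krt4, POSTN, FN1, ctsla and csf1ra, where not covered by the rule, were chosen after their values were seen.

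CPM, counts scaled to the same total in every library, were computed from the rounded values of the deposited expected counts and their total in each library, and were not corrected for gene length. Variable genes were sought with edgeR 4.0.16 in R 4.3.3 (glmQLFit with an intercept alone, TMM scaling, trended dispersion and robust estimation). The ratio of each gene's quasi-dispersion to the trend was set against an F distribution (prior degrees of freedom 6.01). The filter was filterByExpr (at least 10 counts per library and 15 in all, scaled to depth), which left 12633 genes and, with a single group, needs counts in every library. TMM factors were 0.760, 1.03, 1.08 and 1.19 in fish 1 to 4. On simulated counts for the 12633 genes, with 50 genes each changed 4-, 8-, 16- and 32-fold in 1 fish, 22, 39, 43 and 29 were called in that order, and 3 of 12433 unchanged genes were called. The simulated counts used the trended dispersion alone, with no extra spread for single genes, and the changed genes had a mean of at least 50 counts. The rates may therefore be too high for the real genes. A changed gene that the filter dropped counted as not called. limma 3.58.1 and DESeq2 1.42.0 gave alternatives.

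List levels used the median of log2(CPM + 0.1) and 10000 random lists of the same size. Variability and deviations used 10000 random lists matched on mean expression in 20 bins. A deviation is a gene's log2 CPM in a fish, with TMM scaling, minus its mean over the 4 fish. Ratios of gene pairs used a pseudocount of 0.1 CPM and an exact two-sided sign-flip permutation test, and were called where all 4 fish shared the sign and the mean exceeded 2 SD. Of 32 planned gene pairs, 19 were run. The other 13 had a symbol that fits several IDs or none, or too few counts (fewer than 10 in some library for both genes). All 6 planned pairs of lists were run. Other scalings, filters, pseudocounts and models, other totals for the shares, and leaving out each fish in turn were tried as alternatives. The order of genes along chromosomes came from a RefSeq table of the assembly GRCz12tu and was used only to see which genes neighbour each other. Lists and figures were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.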

Results

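Gene expression was measured by RNA sequencing in the caudal peduncle muscle of 4 adult wild-type zebrafish, 7 days after a precooled probe had been held against 1 flank for 6 s to freeze the tissue. The 4 libraries form a single group, numbered fish 1 to 4, and uninjured muscle was not analysed here. The values below are therefore levels in injured muscle, ratios within a library and differences between fish, and none of them is a change caused by the injury. The libraries held 8608394, 9223149, 13151330 and 8035157 estimated gene counts in fish 1 to 4, and 16859 genes had a count in every fish. Levels are given in CPM, counts scaled to the same total in every library, as mean ± SD over n = 4 fish unless a single fish is named.

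The libraries were dominated by transcripts of fast muscle and of the mitochondrial genome. The 30 genes of the fast contractile list took 16.3% ± 3.72 of all counts and the 13 protein-coding mitochondrial genes took 20.1% ± 3.76. The light chain names mylpfa, mylpfb and mylz3 of the fast list matched no symbol. The fast light chain MYL11, given below, was not in the list, so its counts are not in that share. The fast myosin heavy chain gene myhc4 (ENSDARG00000035438) stood at 45711 ± 15088 CPM and the muscle creatine kinases ckmb and ckma at 22353 ± 3526 and 16815 ± 2789 CPM. MT-CO1, a subunit of cytochrome c oxidase, was the most abundant transcript at 70869 ± 17102 CPM, followed within the mitochondrial list by MT-CO2 at 26972 ± 4470 and MT-CO3 at 24099 ± 3943 CPM. Other genes among the 20 most abundant were the actin gene actc1b (27672 ± 6904 CPM), the fast myosin light chain MYL11 (18077 ± 5084), the calcium pump atp2a1l (14005 ± 3763), the parvalbumins pvalb4 (12044 ± 2793) and pvalb3 (9395 ± 4437), and tropomyosin tpma (11455 ± 3774). The remaining members of that group were MT-CYB, MT-ATP6, MT-ND4, MT-ND2, MT-ND1, nme2b.2, TNNT3 and MYL1. Together the 20 genes took 48.8% of the counts in fish 1 and 37.3%, 37.0% and 35.5% in fish 2, 3 and 4.

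Glycolytic genes took 2.01% ± 0.822 of the counts, led by GAPDH (7871 ± 2642 CPM), ALDOA (ENSDARG00000011665, 4794 ± 3219 CPM) and ENO3 (2281 ± 1200 CPM). Slow contractile genes took 0.406% ± 0.133, led by the slow myosin smyhc2 (1261 ± 530 CPM) and the tropomyosins TPM2 (750.5 ± 301 CPM) and tpm3 (460.4 ± 164 CPM). Only ryr1a was planned for the slow list, but every gene with the symbol RYR1 entered it. Genes of sarcomere assembly and new fibres took 0.541% ± 0.0642. Their leading members were the giant thin-filament protein gene NEB (1984 ± 324 CPM), MYOZ1 (663 ± 180 CPM) and SMYD1 (645 ± 86.7 CPM), and the myosin chaperone hsp90aa1.1 stood at 288 ± 159 CPM.

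Among the 28 lists, extracellular matrix took the largest share after the mitochondrial and fast contractile lists, and genes outside the lists were not ranked. Its 29 genes took 3.88% ± 1.11 of the counts, and the median member stood at 621 CPM. The type I collagen genes COL1A1 (ENSDARG00000035809), COL1A2 and col1a1a reached 5471 ± 1847, 4767 ± 1527 and 4525 ± 1451 CPM. FN1 (ENSDARG00000006526), the gene of fibronectin, stood at 3453 ± 1352 CPM and POSTN (ENSDARG00000104267), a matrix protein of remodelling tissue, at 2867 ± 1267 CPM. Proteases and lysosomal genes took 0.417% ± 0.113, with the matrix metalloproteinase MMP2 at 1183 ± 358 CPM, its regulator TIMP2 at 465 ± 122 CPM and the cathepsin ctsla at 442 ± 160 CPM. Fibroblast and tendon genes took 0.0981% ± 0.0258, led by TAGLN (ENSDARG00000033466, 140 ± 28.1 CPM), VIM (116 ± 41.9 CPM) and CCN2 (111 ± 50.9 CPM).

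The myogenic programme was expressed in all 4 fish. The 21 genes of the list took 0.0582% ± 0.0101 of the counts. Myogenin (MYOG, ENSDARG00000009438), which drives myoblast differentiation, stood at 37.3 ± 22.6 CPM and ranged from 11.7 CPM in fish 1 to 64.1 CPM in fish 2. MYOD1 and MYF5, which specify myoblasts, stood at 29.4 ± 7.80 and 7.86 ± 3.84 CPM, and MYF6 at 5.80 ± 1.89 CPM. The fusion genes MYMK and mymx, which encode membrane proteins that merge myoblasts, stood at 4.47 ± 3.90 and 3.90 ± 1.64 CPM. Both genes with the symbol PAX7, the transcription factor of muscle stem cells, were counted in every fish, at 3.44 ± 1.23 CPM (ENSDARG00000070818) and 2.501 ± 0.768 CPM (ENSDARG00000100398). The most abundant members were the 2 MEF2C genes (153 ± 14.5 and 85.8 ± 10.2 CPM) and JAM3 (ENSDARG00000061794, 75.0 ± 19.9 CPM).

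Of the 3 lists of immune cells, macrophage genes took the largest share. The macrophage, neutrophil and lymphocyte lists held 23, 10 and 16 IDs, and 1, 3 and 2 of their names matched no symbol. The neutrophil gene mpx was among the unmatched names, so the shares compare these lists and not numbers of cells. The macrophage list took 0.0499% ± 0.0232 of the counts, the neutrophil list 0.0121% ± 0.00301 and the lymphocyte and natural killer list 0.00158% ± 0.000372. The scavenger receptor marco (70.7 ± 36.8 CPM), the complement genes c1qc (54.2 ± 24.8 CPM) and c1qb (49.9 ± 19.02 CPM) and the growth factor receptor csf1ra (39.9 ± 16.7 CPM) led the macrophage list. Neutrophil genes were led by srgn (87.7 ± 23.4 CPM), CSF3R (8.66 ± 3.27 CPM) and lyz (7.79 ± 2.68 CPM), and lymphocyte genes by tagapa (3.78 ± 1.77 CPM), ighm (2.53 ± 3.31 CPM) and RUNX3 (2.35 ± 0.453 CPM). Inflammatory signals took 0.0548% ± 0.0191. Their leading genes were the 2 SOCS3 genes, feedback inhibitors of cytokine signalling, at 151 ± 78.0 and 89.1 ± 63.0 CPM, and TGFB3 at 78.6 ± 15.05 CPM. The acute cytokine gene il1b stood at 1.56 ± 2.15 CPM, and IL10 had no count in any fish, which allows at most 0.373 CPM in the shallowest library. Antigen presentation took 0.119% ± 0.0241, led by cd74a (267 ± 104 CPM), b2m (249 ± 38.2 CPM) and b2ml (210.1 ± 36.7 CPM). Interferon response genes took 0.0200% ± 0.00521, with irf9 (28.5 ± 7.96 CPM) and trim25 (27.6 ± 8.03 CPM) among their abundant members.

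Cell cycle genes were counted in every fish. Cell cycle genes took 0.0481% ± 0.0137, with HMGB2 (ENSDARG00000029722) at 79.8 ± 13.6 CPM, the replication clamp PCNA at 59.6 ± 21.6 CPM, hmgb2b at 45.9 ± 11.3 CPM and the proliferation marker mki67 at 16.3 ± 7.72 CPM. Growth and patterning signals took 0.0601% ± 0.0150, led by the retinoic acid synthesis gene ALDH1A2 (143 ± 55.8 CPM), igf2b (95.8 ± 42.7 CPM) and NOTCH3 (92.4 ± 23.5 CPM). Atrophy and autophagy genes took 0.0481% ± 0.00444, led by foxo3b (114 ± 49.2 CPM), MAP1LC3B (79.8 ± 17.2 CPM) and the ubiquitin ligase trim63b (75.7 ± 18.2 CPM). Immediate early and heat shock genes took 0.0587% ± 0.00368, led by NR4A1 (175 ± 129 CPM), JUN (109 ± 26.8 CPM) and JUNB (ENSDARG00000104773, 54.5 ± 22.0 CPM). Circadian genes took 0.109% ± 0.0145, led by tefa (149 ± 24.0 CPM), PER2 (126 ± 25.8 CPM) and PER1 (ENSDARG00000012499, 109 ± 20.6 CPM).

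Other cell types took small shares of the counts. The endothelial list took 0.0636% ± 0.00899 of the counts, with kdrl at 122 ± 18.8, cdh5 at 81.3 ± 11.9 and plvapb at 59.3 ± 19.5 CPM. Nerve and Schwann cell genes took 0.0714% ± 0.0142, with PMP22 at 237 ± 43.6 and mbpb at 116 ± 18.7 CPM. Skin epithelium genes took 0.0726% ± 0.0479, and the keratin krt5 ranged from 4.23 CPM in fish 4 to 545 CPM in fish 1, while krt4 ranged from 322 to 424 CPM and krt91 from 18.1 to 440 CPM. Without krt5 and krt91 the skin list took 0.0429% ± 0.00447, most of it krt4. Bone and cartilage genes took 0.0458% ± 0.0102, led by COL2A1 (ENSDARG00000011407, 235 ± 72.8 CPM) and the 2 COL10A1 genes (95.3 ± 28.3 and 53.5 ± 35.2 CPM). Adipocyte genes took 0.0466% ± 0.00660, led by fabp4a (268 ± 87.7 CPM), LPL (86.9 ± 35.0 CPM) and cfd (83.3 ± 7.07 CPM). Erythrocyte genes took 0.0404% ± 0.0259, led by the globin hbaa1 (340.03 ± 234 CPM), hbaa2 (19.1 ± 16.8 CPM) and cahz (14.3 ± 5.35 CPM). The globin names hbba1, hbba1.1 and hbba2 matched no symbol, so this share leaves those genes out. Pigment cell genes took 0.00100% ± 0.000283 and were led by ltk (2.33 ± 1.24 CPM). Pancreas and liver genes, which were included as a control for visceral tissue, took 0.000996% ± 0.00111 (0.000485% without fish 2), with tfa at 20.3 CPM in fish 2 and 0.684 CPM in fish 3.

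**Figure D1:**
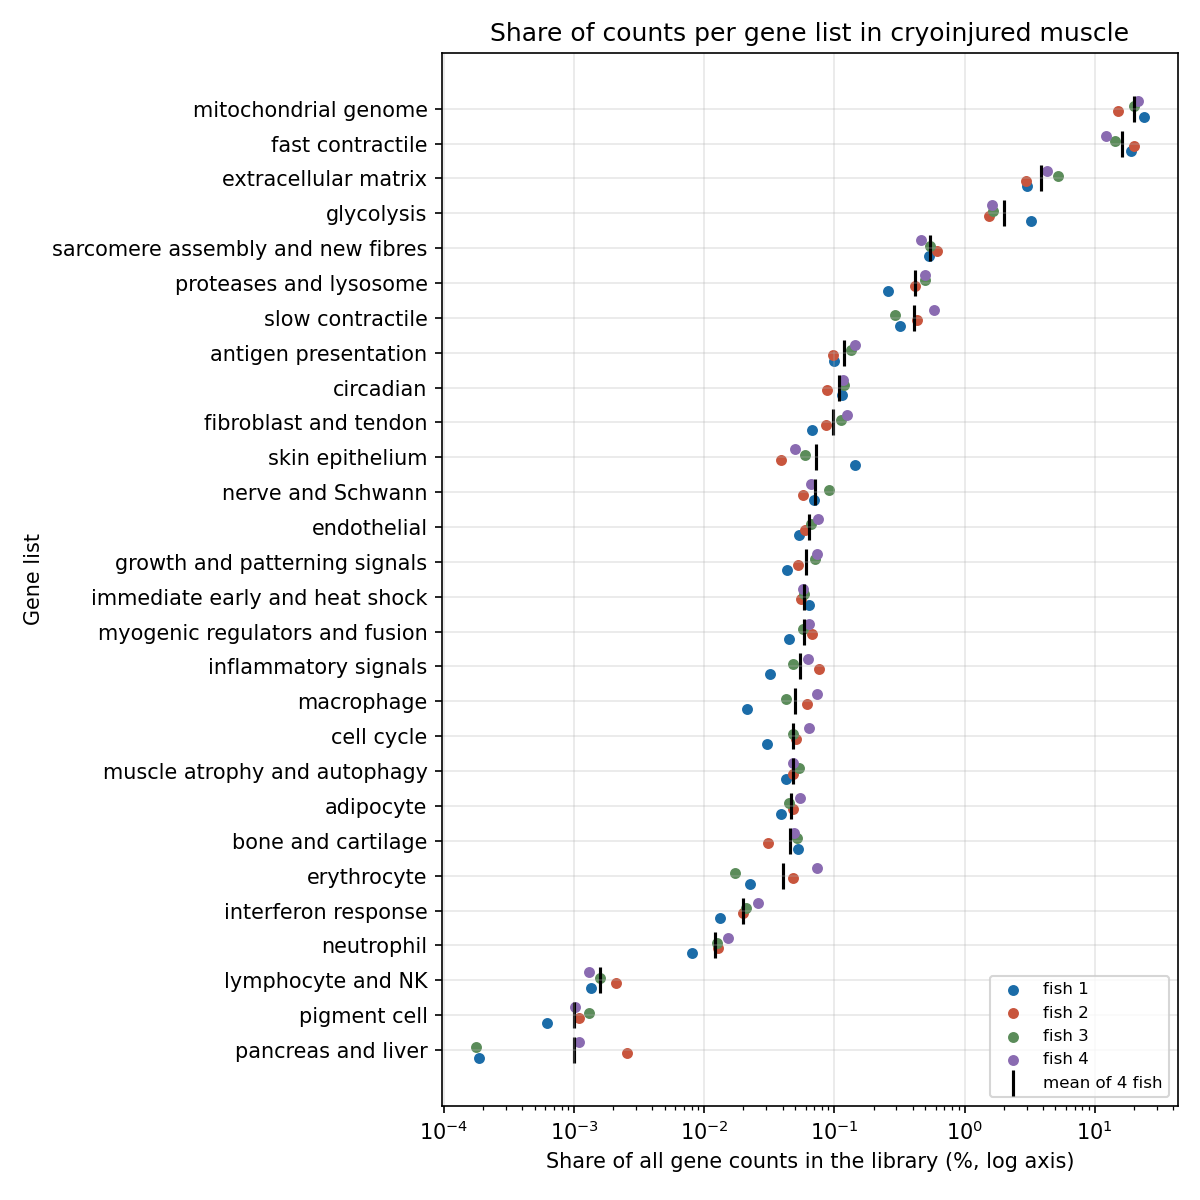
Share of all gene counts taken by each of the 28 gene lists (horizontal log axis, percent) in each fish (coloured points), with the mean of the 4 fish as a black bar. Mitochondrial (20.1%) and fast contractile (16.3%) genes lie highest and pancreas and liver genes (0.000996%) lowest.

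The median level of a list was compared with 10000 random lists of the same size drawn from all counted genes, as a description of these libraries. For 14 of the 28 lists the median lay within the highest 2.5% of the random lists. These were the fast and slow contractile, sarcomere assembly, glycolysis, mitochondrial, extracellular matrix, fibroblast, protease and circadian lists (all at the 100 percentile), the macrophage and endothelial lists (99.99), and the atrophy (99.8), immediate early (99.23) and myogenic (99.11) lists. Cell cycle genes lay at 89.57, inflammatory signals at 94.58 and neutrophil genes at 54.53. Pancreas and liver genes lay at 0. Lymphocyte genes lay at 3.52, and at 2.1, 1.73 and 2.24 without fish 1, 2 or 3, and skin genes lay at 7.19, and at 2.04 without fish 1. Against random lists drawn only from genes that passed the count filter, 10 lists kept that level, and the macrophage (95.9), atrophy (92.8), immediate early (71.3) and myogenic (62.3) lists fell short of it. The fixed lists kept their members that failed the filter (16 of 23 macrophage IDs passed it), which lowers their percentiles in this comparison.

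Ratios within a library compared the members of related gene pairs. MYOD1 exceeded MYF5 by 1.98 ± 0.41 on the log2 scale, and MYF6 lay below MYOG by a log2 ratio of -2.46 ± 0.81. The slow myosin smyhc1 lay below smyhc2 (-2.36 ± 0.72), igf2b above igf2a (3.54 ± 0.25), csf1ra above csf1rb (3.24 ± 0.52), and IGF1 below the muscle growth inhibitor mstnb (-3.09 ± 0.68). tgfb1a lay below TGFB3 (-1.93 ± 0.34) and above TGFB2 (0.77 ± 0.27), CCNB1 below CCND1 (-2.24 ± 0.96), and ckma slightly below ckmb (-0.41 ± 0.13). Myostatin copy mstna had 2 counts in the 4 libraries together, so mstnb was at least 52-fold higher against a floor of 3 counts per library in every fish. MMP9 (23.2 ± 10.1 CPM) was set against mmp13a, which had 1 to 6 counts per library, and cxcl8b.1 (7.04 ± 8.19 CPM) against cxcl8a, which had 0 to 2.

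These 13 of the 19 gene pairs had the same sign in all 4 fish and a mean larger than 2 SD. The other 6 did not meet that rule. MYOG and MYOD1 (0.13 ± 0.69), MYMK and mymx (-0.09 ± 0.65) and PDGFRA and PDGFRB (0.10 ± 0.69) differed in sign between fish. LDHA and LDHB (1.07 ± 0.99), CXCL12 and cxcl12b (-1.29 ± 0.90) and FBXO32 and trim63a (-1.27 ± 0.91) had the same sign in 4 of 4 fish but a spread too large. With 4 fish, the exact two-sided sign-flip permutation test cannot give a p below 0.13, which is the value for every called pair (0.149 after Benjamini-Hochberg adjustment over 25 pairs). Ratios between different genes were not corrected for transcript length. Without fish 2 the ratio of CCNB1 to CCND1 no longer exceeded 2 SD (-2.30 ± 1.16).

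Summed over lists, fast contractile transcripts exceeded slow ones by 5.36 ± 0.67 on the log2 scale, or 40.9-fold. Macrophage transcripts exceeded neutrophil transcripts by 1.93 ± 0.43 (3.81-fold), or by 3.55 ± 0.51 without the most abundant gene of each list (marco and srgn), and lymphocyte transcripts by 4.86 ± 0.76 (29.1-fold), and extracellular matrix lay below fast contractile transcripts (-2.09 ± 0.71). All 4 ratios had their sign in 4 of 4 fish. Their sizes depend on the number of genes in each list and on which names matched a symbol. The neutrophil list lacked mpx, the fast contractile list lacked mylpfa, mylpfb and mylz3, and the slow list held a RYR1 copy that was not planned as slow. Cell cycle against myogenic genes (-0.31 ± 0.24) and endothelial against nerve genes (-0.16 ± 0.30) stayed within 2 SD. The ratio of cell cycle to myogenic genes passed that limit without fish 4 (-0.41 ± 0.16).

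**Figure D2:**
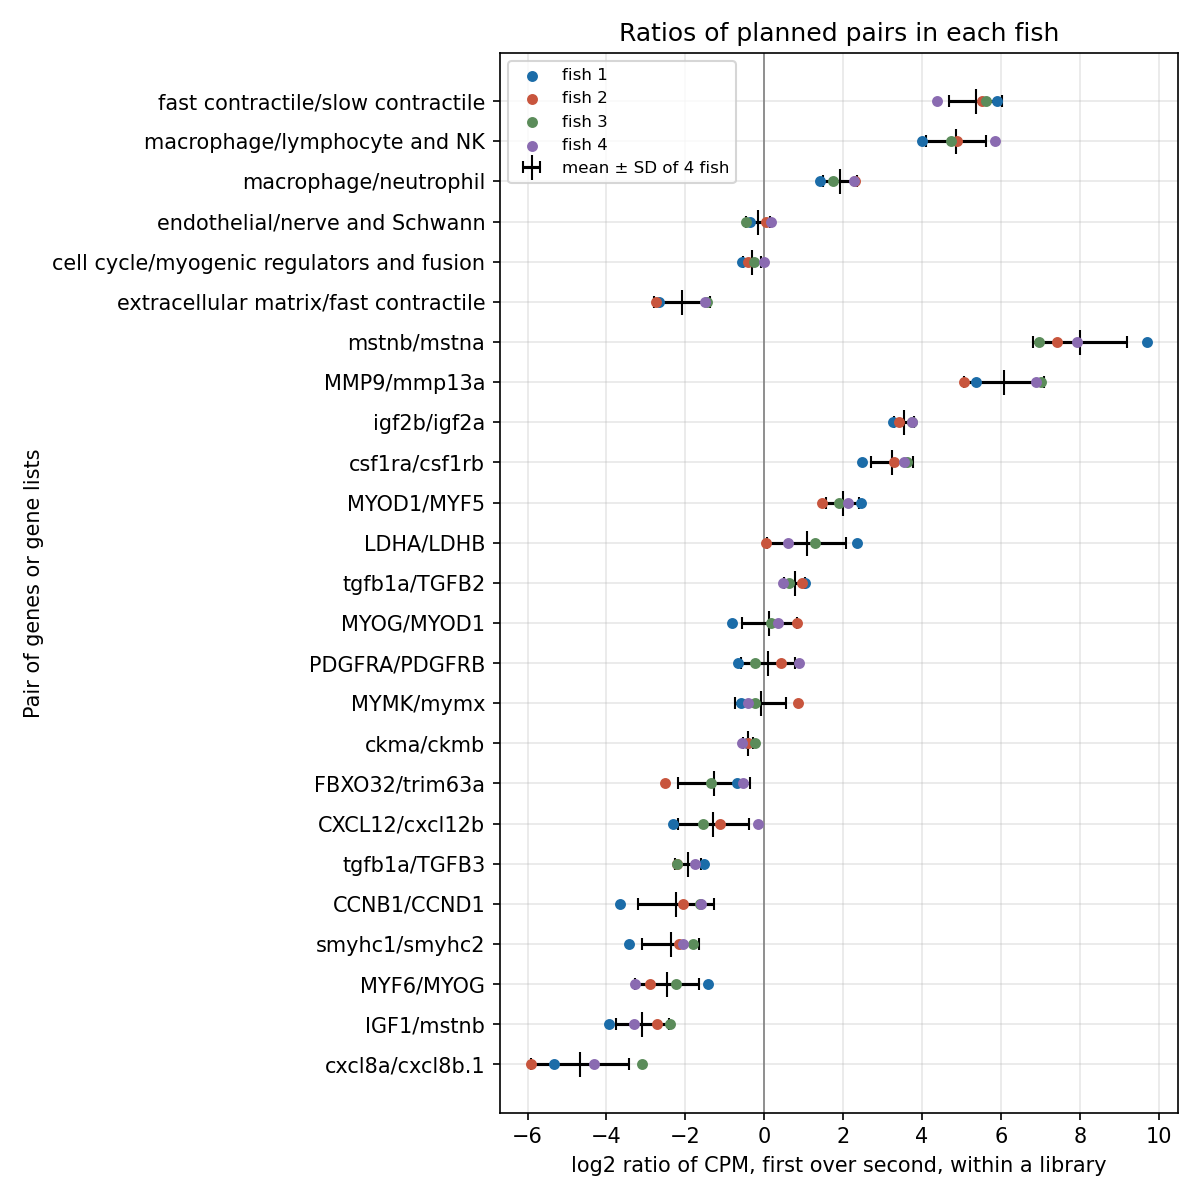
Log2 ratio of CPM within a library (horizontal axis) for each planned pair of genes (lower rows) and of gene lists (upper 6 rows), one point per fish, with the mean and SD of the 4 fish. The ratio of fast to slow contractile transcripts lay between 4.38 and 5.91. Ratios with mstna, mmp13a or cxcl8a rest on few counts and on the pseudocount of 0.1 CPM.

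The second question was which genes differ between fish with the same injury. No gene passed the test for extra variability: 0 of 12633 genes had an adjusted p under 0.05 by edgeR's quasi-likelihood dispersion test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 655 genes, where chance would give 632. The trend and the prior degrees of freedom were fitted to these same genes, which nearly sets that number. The match therefore does not show that the fish differ no more than chance. limma-trend called 0 genes (661 unadjusted), and DESeq2 marked 39 genes as dispersion outliers. On simulated data for the same comparison, 39 of 50 genes with an 8-fold change in 1 fish and 22 of 50 with a 4-fold change were called. At a 32-fold change 29 of 50 were called. Changed genes that the filter dropped counted as not called, and how many were dropped is not given here. The simulated genes had the dispersion of the trend and no extra spread of their own, so these rates may be too high for the real genes. The count of 0 depends on the scaling and on the filter, since 84 genes were called with library totals alone and 248 of 22577 without the filter on low counts. Of those 248 genes, 76 had no count in at least 1 fish, and 120 were among the 12633 genes tested with the filter. Without fish 1, 2 genes passed, the cathepsin gene ctss2.2 (adjusted p = 0.0429, 43.4 CPM in fish 2, 1.22 in fish 3 and 52.4 in fish 4) and a gene with no symbol, ENSDARG00000090901.

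Some gene lists varied between fish more than matched lists. Of 26 lists with at least 3 tested genes, 10 had a median variability within the highest 2.5% of 10000 random lists matched on expression, and 5 passed after Benjamini-Hochberg adjustment over the lists. Those were the fast contractile, glycolysis and macrophage lists (adjusted p = 0.000867 each, from the smallest p of 0.0001 that these random lists can give), slow contractile genes (0.0013) and skin epithelium (0.0052). Genes of a list vary together, which these percentiles do not allow for, so they describe these libraries. By a Fisher test of genes with an unadjusted p under 0.05, slow contractile genes did not pass (adjusted p = 0.107). For glycolysis and skin the result rested on fish 1: without it the percentiles were 19.9 and 75.3. With at least 50 counts in every library the skin list lay at 86.8. The cell cycle list, at the 98.3 percentile with all fish (adjusted p = 0.0861), lay at 35.9 without fish 1. The slow contractile list dropped to 93.3 without fish 3. The myogenic list (26.2), the mitochondrial list (43.3), the extracellular matrix list (68.2) and the endothelial list (65.2) were not within the highest 2.5%. Without fish 1 the extracellular matrix list rose to 99.7 and the mitochondrial list dropped to 0.55.

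Fish 1 had more glycolytic and mitochondrial transcripts and fewer macrophage and proliferation transcripts than the mean of the 4 fish. Its median log2 deviation was 0.94 for glycolysis (15 of 17 genes above the mean), 0.62 for the mitochondrial genome (13 of 13), 0.46 for circadian genes (18 of 21) and 1.06 for skin genes (6 of 6). It was -0.57 for macrophage genes (15 of 16 below the mean), -0.51 for cell cycle genes (23 of 26) and -0.47 for proteases and lysosomal genes (12 of 17). The share of macrophage genes was 0.0212% in fish 1 (exact 95% Clopper-Pearson interval 0.0203 to 0.0222) against 0.0740% in fish 4 (0.0721 to 0.0759), a 3.48-fold range that was 2.23-fold with TMM scaling. In fish 1 marco stood at 35.0 CPM and c1qc at 25.0 CPM, against 119 and 78.3 CPM in fish 4. PCNA stood at 34.5 CPM in fish 1 and 87.0 CPM in fish 4, a range that was 1.62-fold with TMM scaling.

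Fish 2 combined high fast contractile genes (0.55, 25 of 30 genes above the mean) with high macrophage (0.38, 15 of 16), protease (0.29, 11 of 17) and cell cycle genes (0.23, 22 of 26). Its extracellular matrix (-0.37, 23 of 27 below), mitochondrial (-0.36, 11 of 13), nerve (-0.38, 9 of 9), bone (-0.44, 8 of 10), skin (-0.48, 5 of 6) and circadian genes (-0.31, 17 of 21) were low. Fish 3 had the highest extracellular matrix expression (0.40, 27 of 27 genes above the mean) and high nerve (0.29, 9 of 9) and atrophy genes (0.25, 8 of 13). In the same fish the glycolysis (-0.29, 17 of 17 below), slow contractile (-0.39, 12 of 14), fast contractile (-0.25, 27 of 30), macrophage (-0.21, 11 of 16), adipocyte (-0.40, 6 of 7) and erythrocyte lists (-0.38, 6 of 7) were low. Fish 4 had high macrophage (0.37, 15 of 16), slow contractile (0.38, 12 of 14), cell cycle (0.32, 23 of 26) and fibroblast genes (0.18, 11 of 15) and low fast contractile (-0.58, 25 of 30), glycolysis (-0.49, 14 of 17), atrophy (-0.28, 9 of 13) and skin genes (-0.40, 5 of 6).

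The values above, with the fast contractile list in fish 1, are the 35 of 104 whose rank among matched random lists had an adjusted p under 0.05. This rank describes 1 library: its units are genes, which vary together, and no spread between fish enters it, so it does not test a difference between fish. The fast contractile list in fish 1 (0.37, 19 of 30 genes above the mean) changed its sign with the scaling. Scaling by library totals alone shifted the median of all tested genes by -0.40 in fish 1, 0.06 in fish 2, 0.12 in fish 3 and 0.25 in fish 4, and the fast contractile median in fish 1 was then -0.03, still above that shift.

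**Figure D3:**
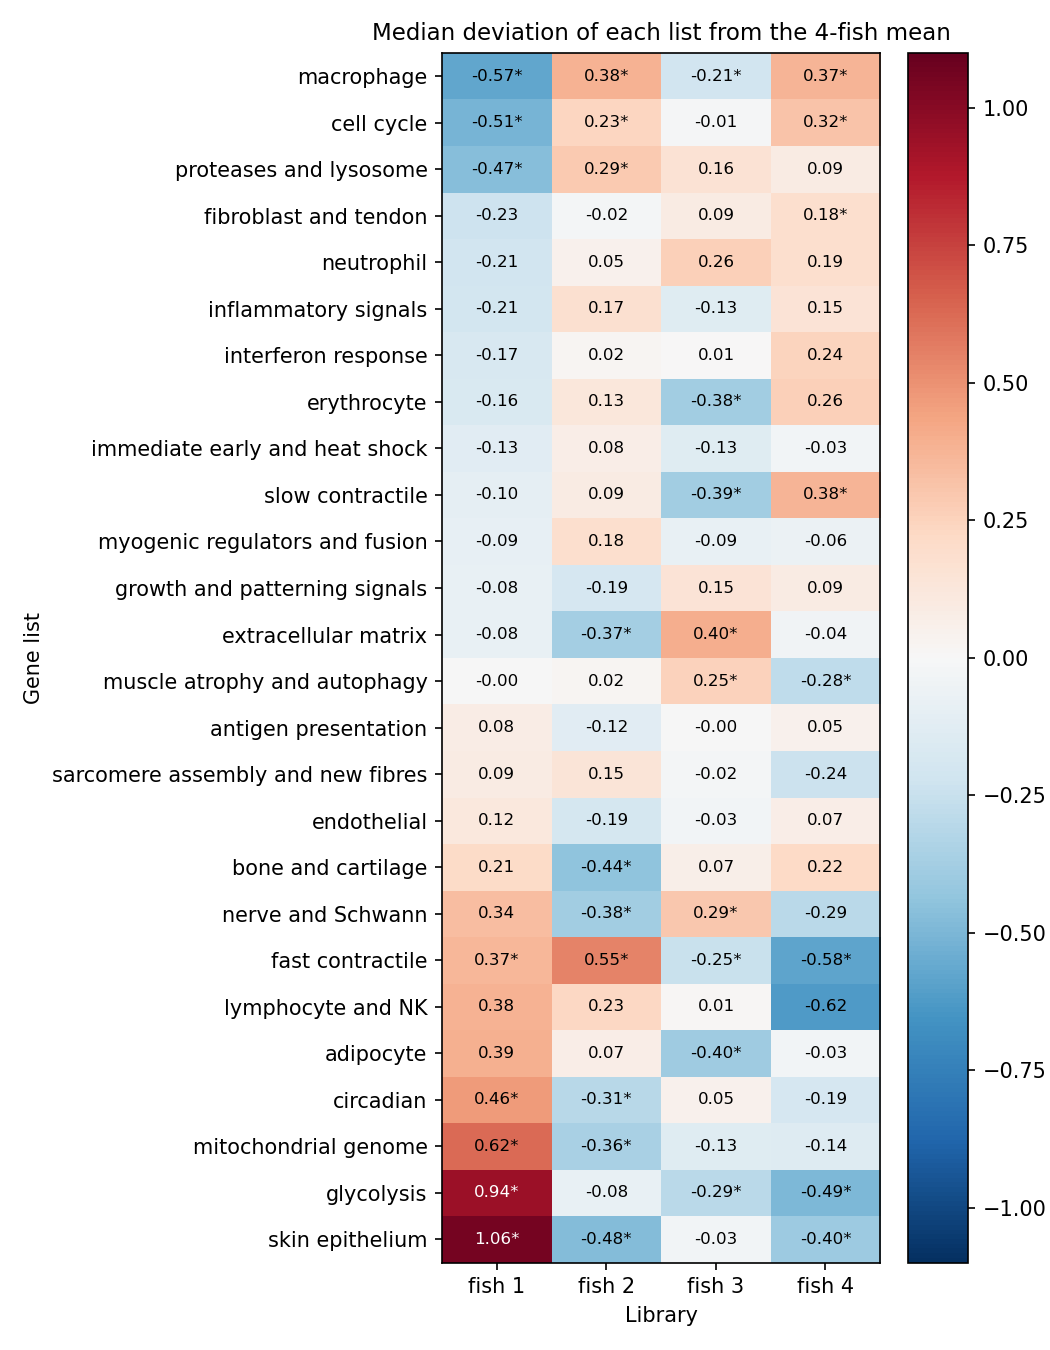
Median log2 CPM deviation of each gene list (vertical axis) from the mean of the 4 fish, in each fish (horizontal axis), after TMM scaling. An asterisk marks a rank among matched random lists with an adjusted p under 0.05, as a description of that library, and with library totals alone the fast contractile value in fish 1 became -0.03. Skin (1.06) and glycolysis (0.94) genes in fish 1 deviate most.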

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

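The tests of explanations in this part were all chosen after the results were seen. Of 182 shares, ratios and named genes, 11 had 1 fish far from the other 3 (the gap to its neighbour divided by the whole range exceeded Dixon's 95% critical value), and about 9.1 would be expected by chance. Fish 1 stood apart in 5, fish 2 in 4, fish 3 in 2 and fish 4 in 0. These values are scaled by library totals, and the count depends on that: with TMM scaling 17 results had 1 fish far from the others, 7 of them among the 11, and fish 1 stood apart in 12, fish 2 in 3, fish 3 in 1 and fish 4 in 1.

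Fish 1 had a much higher level of the skin keratin krt5 (545 CPM against 5.42, 34.8 and 4.23, Dixon ratio 0.943), and krt91 stood at 440 CPM against 18.1 to 92.3. Low depth of the other libraries is argued against, since the level of fish 1 would have given at least 4378 krt5 counts in each. A candidate source is skin or scale tissue left on the piece of fish 1, although the protocol removed skin. Of 15 skin genes with at least 10 counts in a library, 11 were highest in fish 1 in CPM and krt4 (369 CPM in fish 1, 322 to 424 in the others) and TP63 (15.1 CPM in fish 1, 17.1 to 29.3 in the others) were not, although with TMM scaling krt4 lay above its mean in fish 1 (log2 0.36), as did 6 of 6 tested skin genes. Other genes such as the keratin krt97 (159 CPM in fish 1, at most 1.37 in the others) were picked because they were high in fish 1 and decide nothing, so the explanation stays open, and no biological explanation was tested.

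Fish 1 also stood apart in glycolysis (3.24% of counts against 1.53% to 1.66%, ratio 0.924), with ENO3 at 4068 CPM against 1488 to 1806 (0.877) and LDHA at 682 CPM against 306 to 364 (0.846), while its macrophage and cell cycle genes were low. A larger share of muscle fibre RNA would lower the markers of every other cell type alike. As the only cause it is argued against, because endothelial genes deviated by 0.68 more than macrophage genes in fish 1 (bootstrap 95% interval over genes 0.43 to 1.07). That interval resamples genes of 1 library, which vary together, and the macrophage list was chosen because it was low there. A larger share of fibre RNA together with fewer macrophage transcripts was not tested. More uninjured tissue in the piece of fish 1, with its vessels and nerves, may lower the genes of the wound alone. The myogenic list lay at the 19.9 percentile in fish 1, neither with the macrophage and cell cycle lists nor above the middle, so that list did not decide. Outside that test, protease (percentile 0), extracellular matrix (1.37), fibroblast (2.14) and inflammatory genes (3.79) were also low in fish 1. Nerve (97.9), endothelial (88.0) and sarcomere assembly genes (69.1) were not low there. More uninjured tissue cannot be told apart from a milder injury or another pace of healing without uninjured tissue, and no biological explanation was tested.

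The remaining values are given without explanation, and with TMM scaling no fish was far from the others for MEF2C (ratio 0.375), circadian genes (0.608), bone and cartilage genes (0.542) or PMP22 (0.184). With library totals MEF2C (ENSDARG00000009418) was lowest in fish 1 (70.6 CPM against 89.5 to 91.8, ratio 0.889), while with TMM scaling it was highest there. Fish 2 was lowest for circadian genes (0.0879% against 0.115% to 0.119%, ratio 0.853) and for bone and cartilage genes (0.0307% against 0.0490% to 0.0524%, ratio 0.841). It was highest for the immunoglobulin gene ighm (7.48 CPM against 0.498 to 1.16, ratio 0.905) and for mmp13a (0.651 CPM against 0.116 to 0.152, ratio 0.933), which rests on 6 counts. Fish 3 was highest for PMP22 (302 CPM against 209 to 219, ratio 0.896), where with TMM scaling fish 1 was highest, and for mstna, with 2 counts against 0 in the others (ratio 1).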

How the results depend on the processing

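The Fisher test, the shortened skin list and the TMM scaling of single values below were chosen after the data had been seen. The count of 0 variable genes was also found with DESeq2 size factors (662 genes at an unadjusted p under 0.05), a minimum of 50 counts (387), limma-trend (661) and a trend fit that was not robust (626). It became 84 with library totals alone, 248 without the filter on low counts and 39 as DESeq2 dispersion outliers, and leaving out each fish in turn gave 0 to 2. The DESeq2 flag marks genes far above the fitted dispersion and is not an adjusted p under 0.05, so the 39 follow another rule. Of the 248 genes, 76 had no count in at least 1 fish and 120 had been tested with the filter. The prior degrees of freedom changed from 6.01 to 17.7 without the filter and to 468 with library totals alone. With more of them, a large ratio gets a smaller p. The causes of these changes were not tested.

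The number of lists within the highest 2.5% for level was 14 with a pseudocount of 1 and without any 1 fish, and 10 against filtered genes. In that last setting only the random lists were filtered, while the fixed lists kept members that failed the filter. Random lists of filtered genes lie higher by construction, and against them the level percentiles that moved by more than their SD were: circadian 99.4, endothelial 99.2, macrophage 95.9, atrophy 92.8, immediate early 71.3, myogenic 62.3, erythrocyte 17.7, nerve and Schwann 10.6, inflammatory signals 8.21, growth 6.16, adipocyte 1.53, bone and cartilage 1.04, cell cycle 0.23, neutrophil 0.08, antigen presentation 0.01, lymphocyte 0, interferon response 0, pigment cell 0. Lymphocyte genes (1.73 to 3.46) and skin genes (2.04 to 14.8) came within the lowest 2.5% when some fish were left out, lymphocyte genes without fish 1, 2 or 3 and skin genes without fish 1. Level percentiles that moved by more than their SD without 1 fish had these ranges: antigen presentation 59.09 to 88.1, erythrocyte 77.2 to 81.9, fibroblast and tendon 99.99 to 100, growth 90.8 to 94.1, inflammatory signals 90.5 to 96.0, myogenic 98.5 to 99.2, nerve and Schwann 79.7 to 89.5, neutrophil 46.9 to 57.5.

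The number of lists within the highest 2.5% for variability was 10 with DESeq2 size factors, 8 with at least 50 counts and 9 to 10 without 1 fish, and 7 lists passed a Fisher test of genes with an unadjusted p under 0.05. Of the 10 lists, slow contractile (adjusted p = 0.107), atrophy (0.311), bone (0.671) and cell cycle genes (1) did not pass that test, and proteases (0.0369), outside the 10, did. Immediate early (0.00866) and circadian genes (0.0195) passed it but not the adjusted percentiles (0.052 and 0.0748). With at least 50 counts, where fewer genes are tested, growth 98.5, immediate early 89.0, cell cycle 87.7, skin epithelium 86.8 changed side of the threshold. Without fish 1, glycolysis (19.9) and cell cycle (35.9) fell below the middle. Variability percentiles that changed side without 1 fish had these ranges: adipocyte 65.3 to 99.0, antigen presentation 0.09 to 25.4, bone and cartilage 95.5 to 99.8, cell cycle 35.9 to 99.8, circadian 93.0 to 99.8, extracellular matrix 5.44 to 99.7, glycolysis 19.9 to 100, immediate early 82.8 to 99.99, inflammatory signals 69.8 to 98.5, mitochondrial genome 0.55 to 82.9, atrophy 89.6 to 99.2, nerve and Schwann 82.3 to 97.8, sarcomere assembly 69.7 to 99.2, skin epithelium 75.3 to 100, slow contractile 93.3 to 99.99. The causes were not tested beyond the fish left out.

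The gene pairs called numbered 12 with a pseudocount of 1, which lost cxcl8a to cxcl8b.1 (-2.35) because it outweighs the counts of cxcl8a, and 13 to 14 without 1 fish. Ratios that changed their call without 1 fish had these ranges: CCNB1/CCND1 -2.45 to -1.77, CXCL12/cxcl12b -1.67 to -0.95, MYMK/mymx -0.41 to 0.071, cell cycle to myogenic genes -0.41 to -0.22. CCNB1 to CCND1 was lost without fish 2, and CXCL12 to cxcl12b without fish 4, MYMK to mymx without fish 2 and cell cycle to myogenic genes without fish 4 were gained; the causes were not tested. The other list ratios kept their call without any 1 fish, and all 6 without each list's most abundant gene, although macrophage to neutrophil genes then moved from 1.93 to 3.55, cell cycle to myogenic genes from -0.31 to -0.13, and endothelial to nerve genes, which was not called, turned from -0.16 to 0.11. The results with 1 fish far from the others numbered 11 with library totals and 17 with TMM scaling, which raises the values of fish 1 and lowers those of fish 4. The numbers of lists above and below matched lists in each fish were the same with DESeq2 size factors and with library totals alone. They could hardly differ, since a scaling shifts all genes of a library by nearly the same amount. Each list is ranked among random lists of its own library, so these ranks do not test the scaling.

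Shares of counts depend on the total by construction, and none moved by its SD when 1 fish was left out, but the pancreas and liver share, whose SD exceeds its mean, fell to 0.000485% without fish 2. The skin list without krt5 and krt91 took 0.0429%, within the SD of the full list. With mitochondrial genes out of the total, 14 shares moved by more than their SD: fast contractile 20.4%, sarcomere assembly 0.676%, antigen presentation 0.1497%, circadian 0.138%, nerve and Schwann 0.0898%, endothelial 0.0797%, growth 0.0754%, immediate early 0.0738%, myogenic 0.0726%, atrophy 0.0602%, adipocyte 0.0583%, bone and cartilage 0.0579%, neutrophil 0.0152%, lymphocyte 0.00196%. With the 20 most abundant genes left out, 26 moved: extracellular matrix 6.41%, fast contractile 5.91%, glycolysis 3.48%, mitochondrial genome 1.76%, sarcomere assembly 0.904%, proteases and lysosome 0.682%, slow contractile 0.669%, antigen presentation 0.197%, circadian 0.183%, fibroblast and tendon 0.161%, skin epithelium 0.128%, nerve and Schwann 0.119%, endothelial 0.105%, growth 0.0988%, immediate early 0.0986%, myogenic 0.0960%, inflammatory signals 0.0894%, macrophage 0.0806%, atrophy 0.0799%, cell cycle 0.0786%, bone and cartilage 0.0772%, adipocyte 0.0771%, interferon response 0.0328%, neutrophil 0.0199%, lymphocyte 0.00262%, pigment cell 0.00164%.

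Alternatives that need transcript lengths (a correction per kilobase, the longest transcript) were not run, because no lengths were used here, and the Fisher test planned on called genes had no called gene to test. Depth limits the lists of rare cell types: the lymphocyte list rested on 104 to 207 counts per library and the pancreas and liver list on 16 to 233. No paired analysis was possible because the samples form a single group.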

Other observations

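The tests in this part, and all genes named here that are outside the rule for named genes, were chosen after the values had been seen. Some muscle genes differed widely between the fish, although none passed the adjusted test. Fish 1 was lowest and fish 2 highest for the fast myosin genes myhz1.1 (7.09, 124, 31.7 and 56.3 CPM in fish 1 to 4), myhz1.3 (19.2, 217, 43.1 and 50.5) and myhb (16.5, 172, 58.0 and 86.6). The same held for the actin gene ACTC1 (27.6, 367, 174 and 256 CPM), the stress-induced titin partner ANKRD1 (ENSDARG00000075263, 16.3, 266, 100.3 and 229 CPM), the small heat shock gene HSPB7 (5.11, 52.7, 26.5 and 32.4 CPM) and xirp1 (ENSDARG00000030722, 40.4, 313, 256 and 181 CPM). Nestin (nes), an intermediate filament of young muscle cells, stood at 11.5, 64.5, 41.8 and 70.4 CPM. Adult myosin myhc4 did not follow this order, at 58488, 59015, 33815 and 31527 CPM.

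Clock and metabolic genes also differed. The clock repressor nr1d2a stood at 97.7, 14.2, 90.9 and 86.5 CPM in fish 1 to 4, KLF9 at 25.1, 2.39, 28.9 and 14.2 CPM, and LPIN1, a lipid metabolism gene, at 214, 47.2, 155 and 52.6 CPM. Besides krt5 and krt91, fish 1 had the keratin krt97 (159 CPM, at most 1.37 in the others), the enamel matrix genes enam (24.2 CPM, at most 1.14) and scpp7 (16.1 CPM, at most 0.498), and the desmosome genes pkp3a (18.7 CPM, at most 1.22) and dsg2.1 (23.6 CPM, at most 3.73).

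Fish 2 had no count for 5 antigen processing genes that were counted in each of the other 3 fish. PSMB8 had 54, 116 and 67 counts in fish 1, 3 and 4, PSMB9 64, 74 and 21, psmb13a 55, 85 and 39, psmb12 31, 34 and 20, and tap2a 28, 67 and 22. Depth is argued against, since the mean of the other fish would have given at least 26.7 counts of each gene in fish 2. A lower level of the whole programme is argued against too, because 22 other antigen presentation and interferon genes had a median log2 ratio of -0.047 between fish 2 and the mean of the others (bootstrap 95% interval -0.39 to 0.07). A sequence variant of 1 chromosome block in fish 2 is a candidate: the 5 genes fill a window of 5 neighbouring genes of the assembly GRCz12tu. All 4 fish were of the AB strain, so strain does not set fish 2 apart. Of 10000 random sets of 5 counted genes, 0 lay as close. Those sets were drawn from all placed genes, and any cause that acts on the whole block would give the same window. The closeness therefore does not tell a sequence variant from a block that was not transcribed. Only these 5 of the 9 genes with no count in fish 2 and at least 20 in each other fish could be placed. The hypothesis of a variant does not say whether fish 2 lacks the genes or carries copies too different from the reference for its reads to be counted.

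Other immune genes were also near 0 in some fish. The class II gene mhc2dab had 0 CPM in fish 2 and 4, against 12.2 in fish 1 and 23.1 in fish 3, and mhc2daa stood at 46.5, 8.999, 59.5 and 10.1 CPM in fish 1 to 4. The cathepsin ctss2.2 stood at 1.05, 43.4, 1.22 and 52.4 CPM, and 1 of the MFAP4 genes (ENSDARG00000088745) at 3.83, 58.3, 10.7 and 64.8 CPM. The innate receptor genes nlrc8 (0.465 CPM in fish 1, 23.0 to 57.5 in the others) and nlrc11 (0 in fish 3, 25.4 to 54.2 in the others) followed still other fish.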
